A study of Mus musculus with 4 samples.

How the data were processed

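Total RNA of DLA cells from 2 control and 2 irradiated mouse samples was hybridised to one-colour arrays after labelling of 300 ng of RNA with biotin, per the labels' protocols. The labels call the samples biological replicates; whether each came from 1 mouse or a pool is not given in the sources used here. The deposited values were log2 probe set intensities made with RMA (background correction, normalization between arrays and summary of the probes of each probe set), per the submitters' processing notes, which name RMA without a version. The genome build and annotation of that step are not given in the sources used here. The table held 35556 probe sets in each of 4 arrays, rounded to 2 decimals, and 0 columns of other samples. RMA forces a common intensity distribution on the arrays and compresses folds of dim probe sets, so a change shared by most genes cannot be seen and folds are on the array's scale. No scan date or slide was used here, so batches could not be tested.

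Probe sets were named from the platform's annotation table, with symbols updated through Entrez identifiers in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed, and 21698 were found in the RefSeq table. The test used probe sets with 1 symbol, and of the 999 genes with more than 1 probe set the brightest by the mean of all 4 arrays was taken, which left 19938 genes. No genome sequence was used here, and no positions are given.

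Irradiated and control arrays were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend, two-sided) on the log2 values as deposited, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual and 3.48 prior degrees of freedom. A second count took an unadjusted p under 0.05 with at least a 1.5-fold difference. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 31 lists, of which 898 of 1016 entries matched a tested gene. Camera with an estimated correlation and fry were alternatives. Members were also counted at a p adjusted over the list alone.

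The gene lists, the tests, the naming rule and the main alternatives were fixed before the data were examined. The rule named the 15 highest and 15 lowest log2 differences among genes past the adjusted threshold, filled from those past an unadjusted p of 0.05. It required groups that did not overlap, a brighter group mean at or above the median of tested genes, and no predicted or bulk-family symbol. It added up to 4 members with the smallest p of each list reported and 7 genes of the p53 response and proliferation, of which 4 were measured by a probe set with 1 symbol. Members and probe sets named beyond this rule were chosen after their values were seen.

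Alternatives set beforehand were filters on dim genes (25th percentile and median), quantile normalization, centring on the median, the mean of a gene's probe sets, the replicate number as a block, each array left out, eBayes with trend or robust, every row of the table, a fold of 2, and camera on ranks. Cyclic loess, a fit of the 23410 annotated probe sets and further gene lists were added after the data were seen. The procedure was tested on simulated data of 19938 genes, with gene variances drawn from the limma fit and equal in both groups. The irradiated arrays spread more than the control arrays, which the simulation did not copy. In 20 runs limma called 39.05% of genes changed by 1 and 93.55% of genes changed by 2 on the log2 scale, with 146 false calls among 2798. Camera called the list shifted by 0.5 in 20 of 20 runs and 0 of 620 unchanged lists, in simulations where genes varied independently.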

Results

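Dalton's lymphoma ascites (DLA) is a transplantable mouse tumour that grows as free cells in the fluid of the peritoneal cavity. Gene expression was measured in DLA cells taken from Swiss mice that received whole-body electron irradiation of 2 Gy on day 8 after transplantation and from mice that were not irradiated. Cells were collected 48 h after the exposure. The data were 4 one-colour microarrays, 2 control and 2 irradiated, labelled as biological replicates 1 and 2 of each group. Each array held 35556 probe sets, and the array medians lay between 6.43 and 6.46 on the log2 scale. With 2 arrays per group, the number of arrays limited the precision.

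The replicates did not spread equally. Across 19938 genes, which are not independent replicates, the control arrays correlated with r = 0.997, the SD of their difference was 0.167, and 4 genes lay at least 2-fold apart. The irradiated arrays correlated with r = 0.987, with an SD of 0.362 and 230 genes at least 2-fold apart. Irradiated replicate 1 differed from the control arrays with SDs of 0.260 and 0.264, and irradiated replicate 2 with SDs of 0.387 and 0.379. In irradiated replicate 2, 27 genes lay at least 4-fold above every other array, against 0 such genes in each of the other 3 arrays. Prl8a9, of the placental prolactin family, measured 11.47 there and between 4.66 and 5.21 on the others.

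The comparison of irradiated with control cells asked how the messenger RNA of the collected cells differed after whole-body irradiation of the mice. The share of host cells among the collected cells was not measured here. Ly6g, which encodes a surface protein used as a marker of mouse neutrophils, rose 8.69-fold, from 8.85 ± 0.04 in control to 11.96 ± 0.11 in irradiated cells (log2, SD, n = 2 arrays each). Its log2 difference was 3.12 with a standard error of 0.12 (limma adjusted p = 0.0117), and it was the 1 gene of 19938 to pass the adjusted threshold. Ly6f, from the same gene family, was 2.03 higher on the log2 scale without passing it (limma adjusted p = 0.193). Probe sequences were not used here, so signal shared between Ly6 genes was not excluded. In fits of 3 arrays the limma adjusted p of Ly6g was 0.998 and 0.997 without control replicates 1 and 2, and 0.125 and 0.308 without irradiated replicates 1 and 2.

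At an unadjusted p under 0.05, 2055 genes differed in limma, where chance gives 997. Of these, 473 differed at least 1.5-fold, 339 higher and 134 lower in irradiated cells. The count was 315 without control replicate 1 and 1558 without irradiated replicate 1. The groups did not overlap for 8323 genes, 41.7% of those tested, against 33.3% by chance if all arrays spread equally. The irradiated arrays spread more than the controls (SD of the difference 0.362 against 0.167). Unequal spread alone can raise such counts, so the excess over either chance figure cannot be assigned to irradiation. Without irradiated replicate 1 the spread came from the control arrays alone, so more genes could pass. The genes named in the next 2 paragraphs apart from Ly6g passed the unadjusted threshold but not the adjusted one, and their values describe these 4 arrays.

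The neutrophil-attracting chemokines Cxcl2 and Cxcl1 were 2.92 and 2.33 higher on the log2 scale in irradiated cells, which is 7.59-fold and 5.05-fold. Ptgs2, the inducible cyclooxygenase, was 4.35-fold higher. The interstitial collagenases Mmp1a and Mmp1b were 8.08-fold and 4.11-fold higher, and the stromelysin Mmp10 was 3.69-fold higher. Prl6a1 and Prl2c5, members of the placental prolactin family, were 6.89-fold and 3.39-fold higher, and Sprr1a, a precursor of the cornified envelope of keratinocytes, was 6.80-fold higher. The others were Grpr (4.13-fold), Ly6f (4.10-fold), Snap25 (4.07-fold), Nppb (3.85-fold) and Efcab3 (3.52-fold). Several of these differences were uneven between the irradiated arrays, where Prl6a1 measured 8.53 and 10.67 and Ptgs2 had an SD of 1.32, against 6.82 ± 0.01 and 8.51 ± 0.05 in control arrays.

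Among genes lower in irradiated cells, Retnlg, a resistin-like gene of neutrophils, showed a 6.06-fold difference, from 7.52 ± 0.47 to 4.92 ± 0.28 (log2, SD). Srgn, the proteoglycan of blood cell granules, was 2.84-fold lower, and Il1r2, the decoy receptor of interleukin 1, was 2.34-fold lower. Ccn2, Ccn1, Ankrd1 and Amotl2, which are known targets of the YAP and TEAD transcription factors, were 2.11-fold, 2.07-fold, 2.14-fold and 2.17-fold lower. The epithelial keratin Krt7 was 2.28-fold lower. Adm, which encodes adrenomedullin, was 2.33-fold lower. The remaining genes were Fhdc1 (2.57-fold), Acot2 (2.42-fold), Tppp3 (2.23-fold), Spsb1 (2.16-fold), Rnf144b (2.14-fold) and Gcnt3 (2.12-fold).

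**Figure D1:**
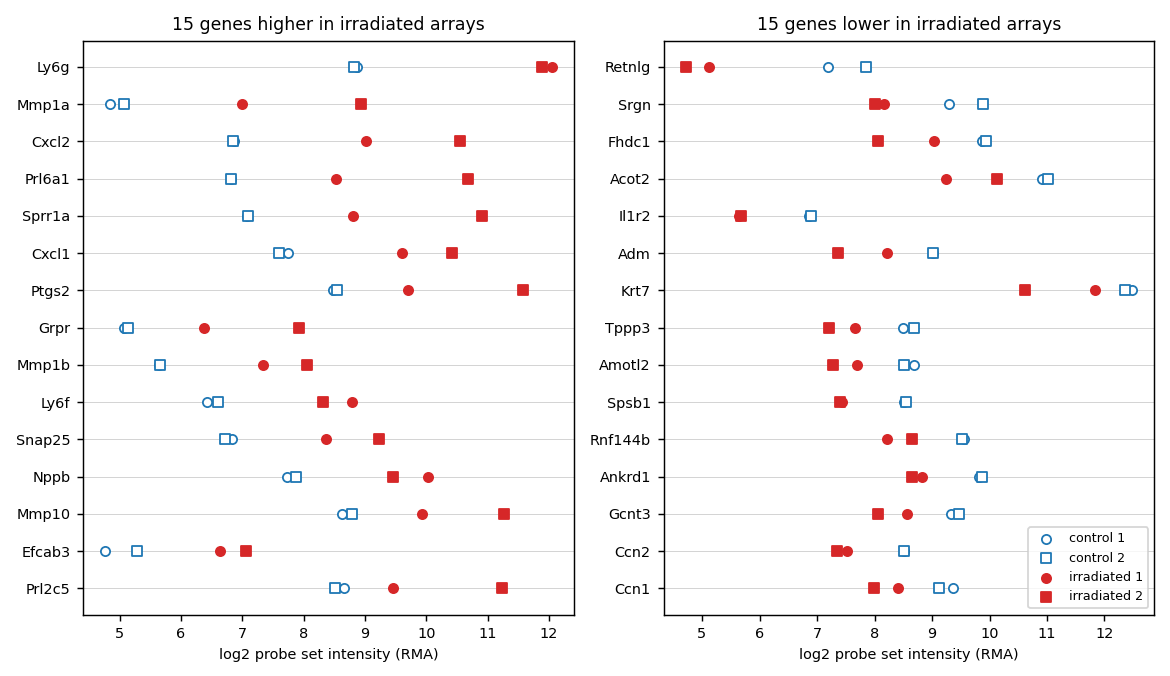
Log2 probe set intensity (horizontal axis) of the 15 genes with the largest positive differences and the 15 with the largest negative differences chosen by the naming rule, with 1 point per array (open, control; filled, irradiated; circles, replicate 1; squares, replicate 2). Both irradiated arrays lie beyond both control arrays for every gene shown, and Ly6g alone passed the adjusted threshold.

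Genes of mitosis were higher in irradiated cells. All 41 measured members of the G2/M and mitosis list had a positive difference, the median was 0.625 on the log2 scale (1.54-fold), and both irradiated arrays lay above both control arrays for 38. Adjusted over the list alone, 26 members rose, 0 fell and 15 did not pass, whereas 0 passed over all genes. Hmmr and Cenpe rose by 1.11 each, Ncapg by 0.81 and Foxm1, a transcription factor of mitotic genes, by 0.78. Mki67, the proliferation marker, rose 1.75-fold, from 10.13 ± 0.00 to 10.94 ± 0.17. The list shifted up in limma's camera test with a preset correlation (adjusted p = 1.95e-28), and the call was lost with an estimated correlation, adjusted p = 0.545. The list median was 0.85 without irradiated replicate 2 and 0.34 without irradiated replicate 1. The same irradiated arrays had adult globin probe sets 9.32-fold to 28.3-fold lower than the controls.

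Genes of DNA replication and repair had smaller positive differences. In the G1/S and DNA replication list, 38 of 41 members were higher with a median of 0.35, and 5 rose adjusted over the list alone, namely Orc1 (0.78), Pola1 (0.76), Rrm2 (0.96), Fen1 (0.54) and Tyms (0.55). In the DNA damage repair list, 26 of 38 members were higher with a median of 0.16, and 0 passed adjusted over the list alone. Its members with the smallest p were Chek2 (0.58), Brca1 (0.49), Rad54l (0.51) and Brca2 (0.47). The replication-dependent histone list had a median of 0.16, 18 of 20 members higher and 0 past the threshold over the list alone, led by H2bc14 (0.36), H2bc9 (0.35), H3c7 (0.63) and H4c6 (0.30). Camera adjusted p-values in limma were 9.24e-14, 3.34e-05 and 1.88e-03 for the 3 lists in this order. All 3 had an adjusted p = 0.545 with an estimated correlation. Without irradiated replicate 2 the medians were 0.53 for the G1/S, 0.2325 for the repair and 0.1625 for the histone list. Without irradiated replicate 1 they were 0.275, 0.1175 and 0.205.

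Inflammatory genes shifted up as a group. Of 37 measured cytokines and NF-kB targets, 25 were higher and 12 lower, with a median difference of 0.52. Adjusted over the list alone, 15 rose, 0 fell and 22 did not pass. Beside Cxcl1, the members with the smallest p were Ier3 (1.21), Traf1 (1.28) and Tnfaip2 (1.22). Csf3 and Csf2, growth factors of granulocytes and macrophages, rose by 1.30 and 1.14, and Nfkbia, the inhibitor of NF-kB, by 0.52. The median was 0.485 without irradiated replicate 1 and 0.29 without irradiated replicate 2. The camera test in limma gave an adjusted p = 4.42e-09, and an adjusted p = 0.545 with an estimated correlation. The neutrophil list of the same arrays had a median of −0.23. The immediate early gene list moved in both directions, with 8 of 28 members rising and 4 falling adjusted over the list alone. Jun, Nr4a2 and Fosl2 rose by 1.11, 0.66 and 0.67, while Ccn2 and Ccn1 fell by 1.08 and 1.05 and Myc fell by 0.68. The median of the immediate early list was 0.35 without irradiated replicate 2 and −0.02 without irradiated replicate 1. Its camera adjusted p in limma was 7.10e-03, but 0.673 without irradiated replicate 1, and the adjusted p = 0.926 with an estimated correlation.

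The 5 other lists past the camera threshold had small median differences, with 0 members past the threshold over the list alone. Oxidative phosphorylation genes had a median of 0.12 (31 of 40 higher), led by Cyc1 (0.52) and Atp5pb (0.41), NRF2 and antioxidant genes one of 0.07 (22 of 34 higher), led by Gpx1 (0.62) and Gsta4 (1.04), and MHC class I genes one of 0.20 (12 of 17 higher), led by Psme2 (0.38) and Tapbpl (0.34). Cytosolic ribosomal protein genes had a median of −0.18 (28 of 31 lower), led by Rpl12 (−0.68) and Rpl22 (−0.34), and glycolysis and hypoxia genes one of −0.15 (26 of 34 lower), led by Adm (−1.22) and Aldoc (−0.66). Camera adjusted p-values in limma were 1.88e-03, 0.0147, 0.0378, 7.80e-04 and 0.0378. With an estimated correlation the adjusted p-values were 0.545, 0.545, 0.918, 0.918 and 0.926. Without irradiated replicate 2 the adjusted p was 0.143 for ribosomal and 0.115 for NRF2 genes, and the direction of the glycolysis list turned (adjusted p = 0.561). The MHC class I list had an adjusted p of 0.566 without irradiated replicate 1 and 0.126 without control replicate 2, and the glycolysis list one of 0.104 without control replicate 1. Without irradiated replicate 2 the medians were −0.07 for ribosomal and 0.01 for glycolysis genes, and without irradiated replicate 1 they were −0.29, −0.30 and, for MHC class I, 0.09. For NRF2 genes the median was 0.0725 without irradiated replicate 2 and 0.095 without irradiated replicate 1.

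Targets of p53, the transcription factor of the DNA damage response, showed no shift as a group at this precision. The list of 38 genes had a median difference of −0.01, 18 members higher and 20 lower, 0 past the threshold over the list alone, and a camera adjusted p in limma of 0.978. The members with the smallest p were Polk (0.43), Gtse1 (0.48), Plk2 (−0.70) and Xpc (−0.58). The list median was 0.01 without irradiated replicate 2 and −0.05 without irradiated replicate 1. Mdm2, the main negative regulator of p53, measured 5.68 ± 0.09 in control and 5.74 ± 0.08 in irradiated arrays (limma adjusted p = 0.90), and Ccng1 was 1.26-fold lower (limma adjusted p = 0.445). Of the 7 genes that were to be given whatever their value, 3 were not analysed here, namely Cdkn1a, Trp53 and Bax. The list result therefore does not cover the p53 targets Cdkn1a and Bax.

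Markers of neutrophils moved apart. Adjusted over the list alone, 8 of 28 neutrophil genes fell, 2 rose and 18 did not pass, with a median of −0.23. The median was −0.39 without irradiated replicate 1 and −0.205 without irradiated replicate 2. Retnlg and Il1r2 fell by 2.60 and 1.23, the chemokine receptor Cxcr2 by 1.16, and the calgranulins S100a9 and S100a8 by 1.00 and 0.80, while Ly6g rose by 3.12 and the gelatinase Mmp9 by 1.28. The list shifted down in limma's camera test (adjusted p = 1.88e-03), with an adjusted p = 0.545 with an estimated correlation and 0.143 without irradiated replicate 1. Among genes with a mean over all arrays at or above the median the direction turned (adjusted p = 0.0257), a filter that kept 5 members, Ly6g and Mmp9 among them, and 0 of those that fell. These arrays also differed in adult globin signal. In a fit of all annotated probe sets, added after the values were seen, 2 probe sets listing both copies of the adult α-globin gene fell 28.3-fold and 22.1-fold (limma adjusted p = 0.00729 for each), from 11.11 ± 0.14 to 6.29 ± 0.23 and from 10.81 ± 0.16 to 6.34 ± 0.09. The 2 probe sets listing several copies of adult β-globin fell 9.32-fold and 11.6-fold (limma adjusted p = 0.00831 and 0.0120). Each of these calls held in 2 of 7 settings and was lost in every fit of 3 arrays. Over these settings the log2 differences ran from −4.99 to −4.355 for α-globin and from −3.695 to −3.115 for β-globin.

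**Figure D2:**
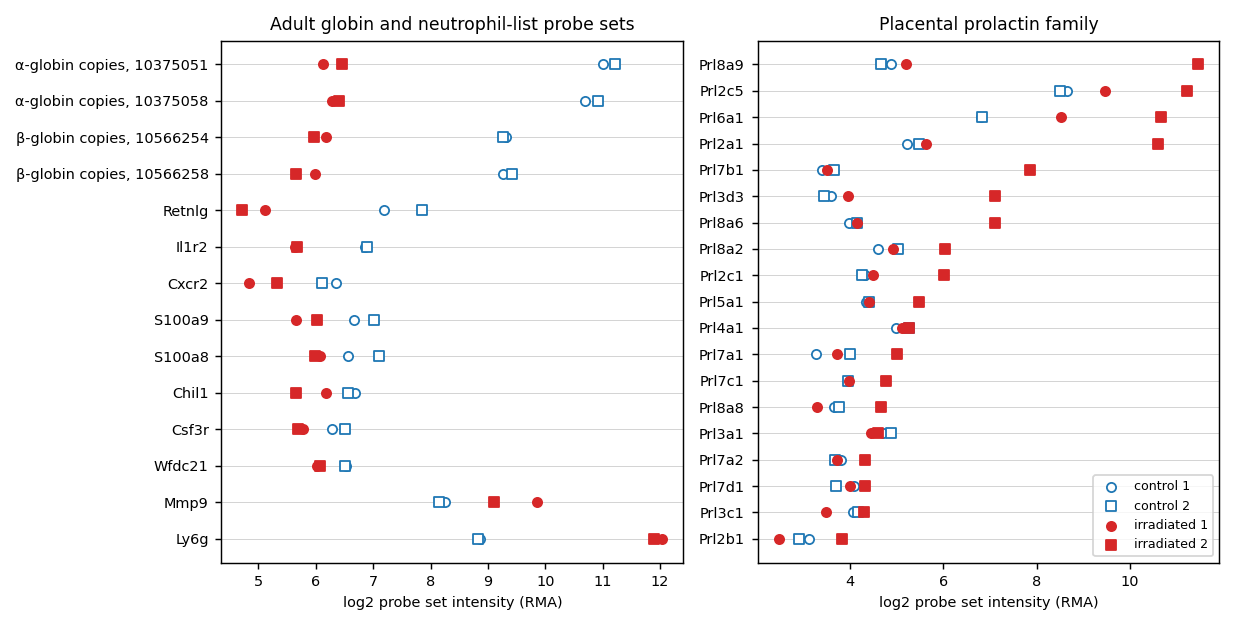
Log2 probe set intensity (horizontal axis) per array of the adult globin probe sets with the neutrophil-list genes that passed over the list alone (left) and of the placental prolactin family (right), with open symbols for control, filled for irradiated, circles for replicate 1 and squares for replicate 2. The 4 globin probe sets lie between 9.27 and 11.21 in control and between 5.65 and 6.45 in irradiated arrays, and Prl8a9 stands at 11.47 in irradiated replicate 2 alone.

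**Figure D3:**
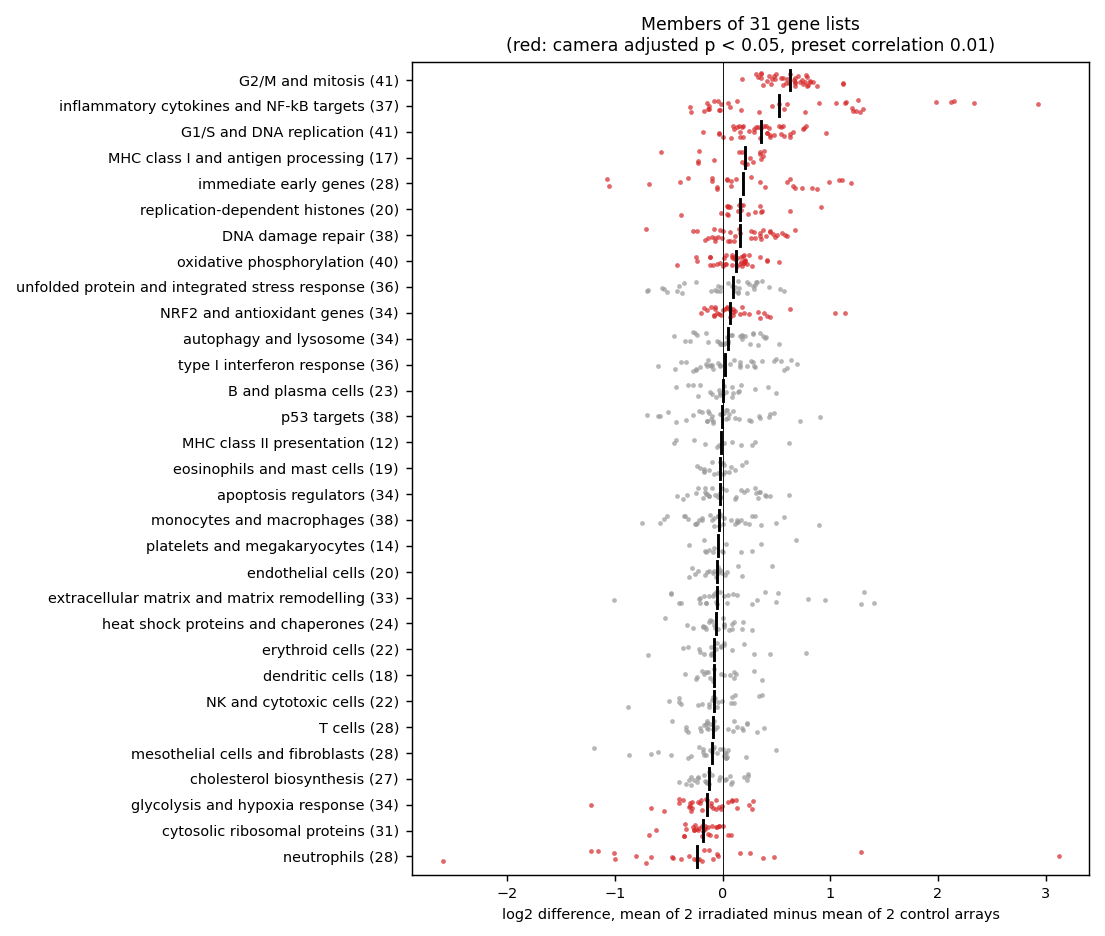
Log2 difference of irradiated minus control means (horizontal axis) for each measured member of the 31 gene lists (points; number of members in parentheses), with the median as a black bar and lists past the camera threshold with a preset correlation in red. All 41 members of the G2/M and mitosis list lie above 0, and 0 lists passed with an estimated correlation.

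The other 19 lists did not pass. They were those of type I interferon response, apoptosis regulators, heat shock proteins, unfolded protein response, cholesterol biosynthesis, MHC class II, extracellular matrix, autophagy and lysosome and p53 targets, and the remaining 10 of the 11 cell type lists (T, B, NK, dendritic, erythroid, endothelial and mesothelial cells, macrophages, eosinophils and platelets). Their camera adjusted p-values in limma ran from 0.131 to 0.978 and their medians from −0.13 to 0.10. Summed over these lists, 1 member rose and 2 fell adjusted over the list alone. The unfolded protein list had a median of 0.2375 without irradiated replicate 1 and −0.09 without irradiated replicate 2. The macrophage mannose receptor Mrc1 was the 1 that rose on all 4 arrays together (0.90), and Clec4e (−0.75) and Mthfd2 (−0.70) were the 2 that fell. Median, mean and test direction did not share 1 sign for the lists of apoptosis regulators, extracellular matrix, platelets, unfolded protein response, p53 targets and MHC class II. Without irradiated replicate 2, the unfolded protein list turned downward past the camera threshold in limma (adjusted p = 0.0102) and the apoptosis list passed upward (0.0496). Without irradiated replicate 1, the unfolded protein list passed upward (0.0144), as did the autophagy list (0.00942), and the mesothelial list passed downward (0.00585).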

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

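The tests in this part were chosen after the results were seen, except the count of other splits of the arrays. Camera without an array and with an estimated correlation had been planned as alternatives. Their use on the explanations of the G2/M shift was set after their values were known. One probe set outside the main comparison, listing both copies of Ly6c, was higher in irradiated arrays by 1.84 on the log2 scale (10.28 ± 0.03 against 12.12 ± 0.04, limma adjusted p = 0.0450 over all annotated probe sets). It drew attention as a signal above the control level in data the main comparison left out. The call held in 2 of 7 settings, while the log2 difference ran from 1.81 to 1.87. A further probe set of the same 2 genes was higher by 1.83 without passing (limma adjusted p = 0.216).

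Genes of the G2/M list were higher in irradiated arrays, with 38 of 41 above both controls in each. Irradiated replicate 1 carried more of the shift but not all of it, since without it the list median was 0.34 and the camera adjusted p 2.81e-11. A lower share of host cells stayed open: 100 percent of 10000 random lists matched on intensity had a lower median than 0.625, but RMA holds such medians near 0 and the lists were not specific to tumour cells. Genes of 1 programme varying together between samples also stayed open, because the call was lost with an estimated correlation (adjusted p = 0.545) while the list median differed by 0.41 between irradiated replicates and by −0.02 between controls. The 3 splits of 4 arrays are too few to exclude chance, with 1 split, the real one, reaching a shift of 0.625 and the highest other 0.225; an effect of irradiation remains an untested biological explanation.

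Adult globin probe sets and most neutrophil genes were lower while Ly6g was higher. The other 27 members of the neutrophil list did not rise together with Ly6g, which rose by 3.12. They do not decide whether more neutrophils were its source. Their median was −0.235 (SD 0.70) with 22 of them lower, S100a8 and S100a9 fell and only Mmp9 rose over the list alone. The rule for this test was reworded 2 times after its value was known. It set the list against a difference as large as that of Ly6g, which left it little room to fail. Most of these members were dim. Of the 5 list members with a mean at or above the median of all genes, 2 rose (Ly6g and Mmp9) and 0 fell. A smaller share of blood cells could lower globin and neutrophil genes and stayed open. The erythroid list, which held no several-symbol globin probe set, had a median of −0.075 (SD 0.29). For 26 pan-leukocyte genes listed afterwards the median was −0.10 (17 lower, camera adjusted p = 0.167 in limma). Of these, Srgn and Cd52 fell and Lcp1 rose over the list alone. The pan-leukocyte median was −0.0775 without irradiated replicate 2 and −0.15 without irradiated replicate 1. Cross-hybridisation among Ly6 genes cannot be told apart from a true Ly6g increase without probe sequences. Of 12 family members with a probe set of 1 symbol, 2 rose adjusted over that list alone (Ly6g and Ly6f). The 12 leave out the 2 Ly6c probe sets, which were higher by 1.84 and 1.83. Bleeding into the cavity at collection and an effect of irradiation on the host were not tested.

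Most placental prolactin genes were higher in irradiated replicate 2 than in irradiated replicate 1. Of 19 measured members, 7 lay above both controls in both irradiated arrays, Prl6a1 and Prl2c5 among them. Prl8a9 measured 11.47 in irradiated replicate 2 and between 4.66 and 5.21 on the other arrays. Between the irradiated arrays, 13 of 19 measured family members differed at least 2-fold. Some of the 13 were at low intensity on both, as Prl2b1 at 2.47 and 3.82 and Prl8a8 at 3.30 and 4.67. Cyclic loess removes only a smooth trend with intensity, and left a median difference of 1.14 (SD 1.76), against 1.35 before. Such a trend thus did not account for most of the difference. Other faults of the array were not tested, and the family was listed after its members stood out on it. A different mix of cell types could add such genes. The placental genes Tpbpa, Tpbpb, Cts7 and Ctsq differed by a median of 0.47 at low intensity, which decides nothing. The design gives no group that separates the 2 irradiated samples, so no biological explanation was tested.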

How the results depend on the processing

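Cyclic loess and the fit of all annotated probe sets were chosen after the data were seen; the other settings were planned. Counts of genes and lists were compared with alternatives, as were the SDs of the difference between replicate arrays. These values stayed within 1.5 times in 59 comparisons and moved further in 20. The number of genes past the adjusted limma threshold was 0 over every row of the table, 0 without any 1 array (range 0 to 0) and 6 over all annotated probe sets, 5 of them with several symbols. Ly6g kept its direction in all 13 settings (3.04 to 3.20) and passed in 8. The replicate numbers are shared by the groups but pair nothing known (correlation of deviations across genes 0.068); with the number as a block 0 genes passed, and Ly6g had an adjusted p of 0.370. Genes past the unadjusted p with a 1.5-fold difference numbered 315 to 1558 when 1 array was left out (209 to 905 higher, 106 to 653 lower), 1060 over every row (669 higher, 391 lower) and 91 at a fold of 2 (73 higher, 18 lower). In fits of 3 arrays the lone array is assumed to vary like the other group. Without an irradiated array the spread comes from the closer control pair, which can raise the counts. By list, 385 results kept their side of the threshold, 33 were lost, 5 were gained and 3 turned. A change of direction was counted as a turn only where the list passed in the main test or in the alternative. Changes of direction where neither passed are among the 385. With an estimated correlation 0 lists passed, at adjusted p-values of 0.545 for DNA repair, G1/S, G2/M, histones, inflammatory, NRF2, oxidative phosphorylation and neutrophil lists, 0.918 for ribosomal and MHC class I lists and 0.926 for immediate early and glycolysis lists. With fry 0 lists passed, at 0.331 for DNA repair, G1/S, G2/M and NRF2, 0.278 for histones, 0.111 for inflammatory and neutrophil, 0.760 for immediate early and glycolysis, 0.326 for oxidative phosphorylation, 0.512 for ribosomal and 0.729 for MHC class I lists. The glycolysis list had an adjusted p of 0.0714 with genes below the 25th percentile left out and 0.0738 after quantile normalization. The neutrophil list turned upward among genes at or above the median (0.0257). With 1 array left out, adjusted p-values ran from 1.84e-05 to 0.561 for glycolysis (turned without irradiated replicate 2), 0.00079 to 0.566 for MHC class I, 1.27e-06 to 0.673 for immediate early, 0.00154 to 0.143 for neutrophil, 0.0156 to 0.115 for NRF2 and 8.37e-06 to 0.143 for ribosomal genes. For the unfolded protein list they ran from 0.0102 (downward without irradiated replicate 2) to 0.957, with 0.0144 upward without irradiated replicate 1. The lists gained were this one, autophagy (0.00942) and mesothelial cells (0.00585) without irradiated replicate 1, apoptosis (0.0496) without irradiated replicate 2 and mesothelial cells (0.0412) among genes at or above the median. The cause was not tested. Many list members of cell types lay near the low end of the intensity range, where the arrays resolve differences least.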

Other observations

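All values and tests in this part were chosen after the data were seen. Across the 4 arrays, the keratins Krt8, Krt18, Krt19 and Krt7 measured high, between 10.62 and 14.11, while trophoblast genes covered a wide range of intensity. Krt8 measured between 13.30 and 14.11, Krt18 between 12.64 and 13.45, Plet1 between 13.10 and 13.85 and Eomes between 9.95 and 10.42, and the trophoblast genes Elf5 and Esrrb between 5.27 and 5.55 and between 4.79 and 5.21. The median level was 5.62 for the T cell list, 5.66 for the B and plasma cell list and 6.15 for 26 pan-leukocyte genes. It was 7.52 for 28 trophoblast genes. Levels of different probe sets cannot be ranked as amounts of RNA. A list of 28 trophoblast genes had a median difference of −0.05, with 13 members higher, 15 lower and 0 past the threshold over the list alone. The trophoblast median was −0.095 without irradiated replicate 2 and −0.025 without irradiated replicate 1.

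Of 23 known YAP and TEAD targets, 7 fell and 1 rose adjusted over the list alone. Axl was the 1 that rose (0.71), and Ankrd1, Ccn2, Amotl2, Nt5e, Lats2, Ccn1 and Crim1 fell by 1.10, 1.08, 1.12, 0.77, 0.87, 1.05 and 0.45. The list, written after its leading members were seen, had a camera adjusted p of 0.0104 in limma over 6 such lists. With an estimated correlation the camera adjusted p was 0.606. The list median was 0.02 without irradiated replicate 2 and −0.29 without irradiated replicate 1. Lower YAP and TEAD activity may be a hypothesis for these genes. Leaving out the 6 members seen first, the other 17 had a median of 0.03 (SD 0.32) with 8 lower and 9 higher, and a camera p of 0.853, which decides nothing.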
